A study of Homo sapiens with 6 samples.

How the data were processed

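RNA from 22Rv1 cells was measured by sequencing of polyadenylated RNA in 6 libraries. 22Rv1 is an established human prostate cancer cell line. The groups were vehicle, Drug_0120 (named 0120-0018 in the treatment protocol) and Drug_CN27, with 2 libraries each, and groups and replicate numbers were taken from the labels. Per the labels' protocols, each compound was given at its IC50, the concentration that gives 50% of its maximal inhibition; the concentrations and durations are not given in the sources used here.

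The authors deposited a table of TPM values (transcripts per 1000000) per gene, with 1 column per library. The aligner STAR, the assembler StringTie and the genome build hg19 are listed per the submitters' processing notes; their versions, the annotation, the strandedness of counting and any filters are not given in the sources used here. Gene identifiers in the table carry the suffix of GENCODE annotation lifted to the older build, so no coordinates are given, and GENCODE release 29 was used only for gene names, gene type, exon number and the GC content of transcripts. The table had 20315 rows, and 18 second copies of pseudoautosomal genes were left out, which kept 20297 genes. Of these, 19751 identifiers had a symbol in the name table, 19577 had a GC value and 19826 were protein-coding in GENCODE release 29. A spreadsheet had turned 27 symbols into dates, and all 27 were named again from their identifiers. No gene of the mitochondrial genome was in the table.

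The TPM values in the table summed to less than 1000000 in every library, so genes outside the table held the rest. That rest was 18.7% ± 0.829 (SD, n = 2) in vehicle, 28.4% ± 0.604 in Drug_0120 and 19.0% ± 0.857 in Drug_CN27. TPM keeps no sequencing depth, so the depth of the libraries is unknown and no counting interval can be given. Because TPM is relative to the total, a change in the rest moves all genes of the table together.

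Values were analysed as log2(TPM + 1), so fold changes are on the log2(TPM + 1) scale and understate the change of genes with low TPM. The 13606 genes with at least 1 TPM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend). All 6 libraries entered a single fit without a replicate block, and the comparisons were each compound against vehicle and Drug_CN27 against Drug_0120. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05, and intervals are 95% confidence intervals from the same fit. With 3 residual and 5.33 prior degrees of freedom, the test rests largely on the spread pooled over genes. Nothing says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

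Before the data were examined, 35 gene lists were fixed, along with the fit, the named-gene rule and the alternatives. The 29 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation, camera tests on the 3 residual degrees of freedom, so calls can be lost without correlated members. Camera compares a list with the other genes, while fry tests whether members move on balance in a single direction. The lists of mitochondrial genes and of nuclear long non-coding RNAs and snoRNA host genes had no member in the table, and 4 other lists had under 5 tested members. Counts of genes in a list are given over all tested genes and, in those words, adjusted over the list alone. Some genes are in several lists, such as SESN2 among ATF4 and p53 targets and LDHA among glycolysis and MYC genes. The list calls are therefore not independent. The 2-fold counts were chosen after the data were seen.

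Named genes followed a fixed rule. For each compound against vehicle these were the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, mean TPM over the 6 libraries of at least 5 and libraries of both groups not overlapping. Between the compounds, 5 of each were taken. The rule also took H1-10 and the other measured linker histone genes, KLK3, MYC and MKI67 in every comparison, and up to 4 members with the largest moderated statistic in the list's direction were named for each list that passed its test. Rows with no symbol, clone names and pseudogenes were left out, and some genes that the rule names are not reported here, and families whose members could not all be named are given as counts. The strand setting was not given, so genes that overlap or share sequence with a close copy are marked as uncertain where named.

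The overlap of the compounds' calls was set beside 100 simulated draws of unchanged groups against the same vehicle libraries and beside the overlap of independent lists. The fits were tested on simulated data drawn from the real means and spread, with 200 genes changed. The changed genes were drawn only from those with higher TPM in vehicle, so recovery among genes with low TPM was not tested. For Drug_0120 against vehicle (12996 genes) the test recovered 92.5% of changes of 0.5 log2 and 100% of changes of 1 and 2 log2, with 10 false calls among unchanged genes. For Drug_CN27 against vehicle (12986 genes) the shares were 80.6%, 100% and 100%, with 16 false calls. For Drug_CN27 against Drug_0120 (12981 genes) they were 83.6%, 100% and 100%, with 18 false calls. In the same order, false calls made up 4.88%, 7.88% and 8.70% of all calls. In both comparisons with Drug_CN27 this share was above what the adjusted p threshold allows on average. Far fewer genes were changed than limma called in the real data, so the error rate there was not measured. The list test ran on 12987, 12977 and 12994 simulated genes, in the same order of comparisons. In each comparison 2 lists were called, the list of p53 targets shifted by 0.5 log2 and another. Which list that was is not recorded. Some lists share genes, so it may hold shifted members and is not known to be a false call.

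The alternatives fixed with the design were other pseudocounts (0.1 and 5), other filters on low values, median-of-ratios scaling, quantile normalization and rescaling without ribosomal protein genes. A fit of the compared groups alone, a replicate block, eBayes without the trend or with robust estimation, a test against a 1.2-fold change, and leaving out each library in turn were also among them. A GC correction, which subtracts from each library a loess curve (span 0.3) of the log2 value, less the gene's mean, on transcript GC content, was added after seeing the data, with and without the replicate block.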

Results

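Gene expression was measured in 22Rv1 prostate cancer cells treated with vehicle or with either of 2 small molecules described as directed at the linker histone variant H1-10 (listed as H1FX). Each of the 3 groups had 2 libraries. Both compounds were given at their own IC50, whose value and duration are not given in the sources used here, so the doses are not known to match. In vehicle, 12943 and 12917 genes had at least 1 TPM, against 12602 and 12554 with Drug_0120 and 13129 and 13138 with Drug_CN27. Replicates correlated across the 13606 tested genes at r = 0.996 in vehicle, 0.996 in Drug_0120 and 0.994 in Drug_CN27. The depth is unknown, since TPM keeps none, and all means below are over n = 2 libraries with their SD.

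The first comparison asks which genes changed with Drug_0120. H1FX (ENSG00000184897.5_2), the transcript of H1-10, fell from 457 ± 9.44 TPM in vehicle to 184 ± 10.7 TPM (log2 change -1.31 ± 0.06 SE); after a correction for transcript GC content, chosen after seeing the data, the change was -0.57. Of the 4 linker histone genes tested, too few for a list test, 2 fell, H1FX among them, and 2 rose, and median-of-ratios scaling gave the same counts. The largest rise was in MMP1, a collagenase, which went from 0.335 ± 0.131 to 212 ± 0.306 TPM, and GDF15, a secreted stress cytokine, rose from 143 ± 0.417 to 5247 ± 225 TPM. CDC20, an activator of the anaphase-promoting complex, fell from 502 ± 16.1 to 30.6 ± 0.333 TPM. Of the 13606 tested genes, 11092 were called by limma, 4903 higher and 6189 lower, and 1571 of the higher and 2743 of the lower genes changed at least 2-fold. The calls were 5564 higher and 5641 lower with median-of-ratios scaling and 5872 and 5289 with quantile normalization. They were 6005 and 5155 after rescaling without ribosomal protein genes, which also sets equal table sums.

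**Figure D1:**
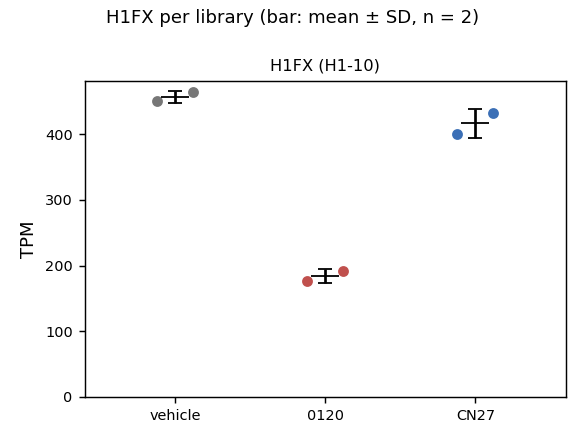
TPM of H1FX in each library (points), with the mean and SD of 2 libraries per group (bars). H1FX was at 457 TPM in vehicle, 184 with Drug_0120 and 417 with Drug_CN27.

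The other large rises with Drug_0120 were in MMP10 (1.09 to 321 TPM), the carboxylesterase CES1 (0.104 to 97.0 TPM) and the activity-regulated gene ARC (1.12 to 147 TPM). The glycoprotein hormone subunit CGA (0.558 to 97.0 TPM), EID3 (1.17 to 104 TPM), the metallothioneins MT1H (0.232 to 56.5 TPM) and MT1G (log2 change 4.76), and PDK4, a kinase that inhibits pyruvate dehydrogenase (18.0 to 479 TPM), also rose. The largest falls were in PIMREG, CHRNA2, HMMR, APLN, KIF20A, NT5DC2, DLGAP5, PLA2G3, CCDC74A and LRRC45, with log2 changes from -4.85 ± 0.14 for PIMREG to -4.26 ± 0.10 for LRRC45. APLN, which encodes the peptide hormone apelin, went from 501 ± 0.780 to 21.9 ± 1.02 TPM. Metallothionein genes and CCDC74A have close copies, so their values are uncertain.

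The median gene moved by -0.10 log2 with Drug_0120 under TPM, by 0.00 with median-of-ratios scaling and by 0.09 after rescaling without ribosomal protein genes. The last of these also removes the group difference in TPM outside the table, so its shift is not that of ribosomal protein genes alone. List medians are given relative to the median of all genes. Of 52 G2/M genes, 47 fell and 1 rose (relative median -2.23), among them PLK1, AURKB and BIRC5. All but 2 of the 52 G1/S genes fell (50, relative median -1.78), with RRM2 at 166 ± 4.68 TPM in vehicle and 16.7 ± 0.622 TPM with Drug_0120, and with E2F2, MCM4 and UHRF1 also lower. MKI67, a marker of proliferating cells, went from 60.6 ± 4.86 to 5.69 ± 0.515 TPM. Of 34 homologous recombination and Fanconi genes, 30 fell and 2 rose (relative median -0.92), including FANCI, EXO1 and FANCA. Camera called these lists at adjusted p = 1.45e-11 for G2/M, 1.45e-11 for G1/S and 1.97e-05 for repair. Their calls were lost at adjusted p = 0.221, adjusted p = 0.106 and adjusted p = 0.244 with an estimated correlation.

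Genes that respond to androgen fell with Drug_0120: 30 of 36 androgen-response genes were lower and 4 higher (relative median -1.28, camera adjusted p = 4.36e-05; adjusted p = 0.244 with an estimated correlation). FKBP5, a cochaperone induced by androgen, went from 717 ± 33.6 to 89.3 ± 5.28 TPM, and DBI, SLC45A3 and SORD also fell. KLK3, which encodes prostate-specific antigen, fell by 2.35 ± 0.18 log2 from a low level of 6.91 ± 1.12 TPM. Of 16 luminal markers, 10 fell and 4 rose, and the list did not pass (adjusted p = 0.343). Of 14 neuroendocrine markers, 11 fell and 3 rose (relative median -1.05, adjusted p = 0.0392; adjusted p = 0.238 with an estimated correlation), among them STMN1, ENO2, SRRM4 and CELF3.

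All 8 metal-response genes rose (relative median 3.65), with the metallothionein MT2A going from 121 ± 5.60 to 2112 ± 189 TPM and MT1E higher by 3.59 ± 0.08 log2. Of 33 immediate early genes, 30 rose and 2 fell (relative median 2.06), with the transcription factor EGR1 at 42.9 ± 0.769 TPM in vehicle and 706 ± 9.43 TPM with Drug_0120, and with FOS, DUSP4 and JUND higher. Of 32 p53 targets, 28 rose and 1 fell (relative median 1.38), with the cell cycle inhibitor CDKN1A going from 350 ± 10.2 to 1791 ± 41.3 TPM and with SESN2 and GADD45A higher. Camera gave adjusted p = 8.15e-06 for metal response, 2.39e-11 for immediate early genes and 4.54e-09 for p53 targets. With estimated correlations of 0.266, 0.0271 and -0.0147 the camera calls were lost, at adjusted p = 0.221, adjusted p = 0.106 and adjusted p = 0.106. For p53 targets the estimate lies below the preset 0.01, so that loss does not come from correlated members. Estimates were also below 0.01 for ATF4 targets (-0.0135), autophagy (-0.0127), MYC (-0.0157), glycolysis (-0.000935) and neuroendocrine genes (-0.0318). Their calls with Drug_0120 were lost likewise.

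Of 37 ATF4 targets of the integrated stress response, 23 rose and 10 fell (relative median 0.71, adjusted p = 0.00133; adjusted p = 0.133 with an estimated correlation), with PPP1R15A, SLC3A2, CHAC1 and SESN2 higher. Of 35 lysosome and autophagy genes, 24 rose and 9 fell (relative median 0.62, adjusted p = 0.000942; adjusted p = 0.133 with an estimated correlation), with MAP1LC3B, an autophagosome protein, going from 62.3 ± 0.498 to 366 ± 0.257 TPM and with SQSTM1, NEU1 and CTSB higher. Of 18 core histone genes, 16 rose and 1 fell (relative median 1.57, adjusted p = 2.07e-05; adjusted p = 0.238 with an estimated correlation); most of these transcripts lack poly(A) tails, and their near-identical copies make HIST1H2AC, HIST1H3H, HIST2H2BE and HIST1H4E uncertain. Of 30 apoptosis regulators, 19 rose and 7 fell (relative median 0.57, adjusted p = 0.023; adjusted p = 0.244 with an estimated correlation). The members that led that list were BBC3, PMAIP1 and TNFRSF10B, which promote cell death, and MCL1, which opposes it.

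Of 40 MYC and ribosome biogenesis genes, 34 fell and 4 rose (relative median -0.76, adjusted p = 4.57e-05; adjusted p = 0.106 with an estimated correlation), with MYC at 229 ± 3.99 TPM in vehicle and 70.5 ± 1.64 TPM with Drug_0120 and with PA2G4 and FBL lower. Of 54 nuclear-encoded respiratory chain genes, 47 fell and 1 rose (relative median -0.70, adjusted p = 2.01e-07; adjusted p = 0.302 with an estimated correlation), among them NDUFB10, ATP5F1B, ATP5MC1 and CYC1. Of 30 glycolysis and hypoxia genes, 21 fell and 8 rose (relative median -0.88, adjusted p = 0.0446; adjusted p = 0.238 with an estimated correlation), with LDHA going from 766 ± 100 to 103 ± 6.49 TPM and with PGAM1, TPI1 and ENO2 lower. Of 76 ribosomal protein genes, 31 rose and 10 fell (relative median 0.22, adjusted p = 0.0276; adjusted p = 0.713 with an estimated correlation), with RPL5, RPS27, RPS6 and RPS12 higher; these genes have many processed copies.

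The lists of chromatin regulators (13 higher and 32 lower of 49, adjusted p = 0.0854), cholesterol synthesis (6 and 17 of 26, 0.0927), fatty acid synthesis (4 and 10 of 17, 0.201) and heat shock (4 and 14 of 20, 0.0578) did not pass. Nor did those of NRF2 targets (15 higher and 10 lower of 27, 0.0839), endoplasmic reticulum chaperones (14 and 8 of 26, 0.131), xenobiotic response (5 and 3 of 8, 0.132) or interferon response (8 and 12 of 28, 0.862). The same held for NF-kB targets (6 higher and 8 lower of 17, 0.944), mesenchymal genes (6 and 6 of 13, 0.893), fibroblast markers (2 and 2 of 6, 0.934) and reference genes (8 and 8 of 17, 0.862). Markers of basal epithelium were 3 higher and 1 lower of 4 tested, and those of leukocytes 2 higher of 3. The endothelial marker ESAM fell. These lists were too short to test. The mesenchymal, NF-kB and fibroblast lists had medians of -0.11, -0.18 and -0.07 and means below 0, while camera's direction was higher. With quantile normalization these medians were 0.05, 0.00 and 0.11. The reference genes had a median of 0.02, a mean of -0.32 and a lower direction. Adjusted over the list alone, the glycolysis list had 8 higher and 22 lower genes, the ribosomal protein list 28 and 10, and the leukocyte list 2 and 1. The other lists kept their counts. The share of TPM outside the table was 28.4% ± 0.604 with Drug_0120 against 18.7% ± 0.829 in vehicle, beside all of these groups. The ribosomal protein list lost its call without vehicle replicate 1 (adjusted p = 0.0889) or without Drug_0120 replicate 2 (0.115), the neuroendocrine list without a filter on low values (0.0543), and the glycolysis list without Drug_0120 replicate 1 (0.0504), Drug_CN27 replicate 1 (0.0504) or Drug_CN27 replicate 2 (0.0502). The heat shock list passed as lower without Drug_CN27 replicate 1 (adjusted p = 0.0496) or 2 (0.0493) and with the GC correction (0.0139), the NRF2 list as higher without vehicle replicate 2 (0.0442), and the chromatin regulator list as lower without a filter on low values (0.0441).

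The second comparison asks the same of Drug_CN27. H1FX was at 417 ± 22.3 TPM against 457 ± 9.44 TPM in vehicle, a log2 difference of -0.13 (95% interval -0.28 to 0.01) that did not pass (limma adjusted p = 0.0918). It was lower than in the vehicle library of the same number in replicate 1 (401 against 450 TPM) and 2 (433 against 464 TPM). With a replicate block it passed as lower. Of the 4 linker histone genes, 2 rose and 0 fell, or 2 and 1 with median-of-ratios scaling. The largest rise was in CHAC1, which degrades glutathione and went from 7.25 ± 0.425 to 390.1 ± 15.2 TPM, and ASNS, asparagine synthetase, rose from 203 ± 1.32 to 2596 ± 103 TPM. CCNB1, cyclin B1, fell from 246 ± 0.116 to 25.2 ± 1.25 TPM. Limma called 9572 of 13606 genes, 5948 higher and 3624 lower, of which 998 and 656 changed at least 2-fold.

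The other large rises with Drug_CN27 were in the cystine transporter SLC7A11 (10.4 to 180 TPM), LAMP3 (0.752 to 23.3 TPM), MIOX (1.21 to 22.5 TPM), the mitochondrial enzyme PCK2 (74.8 to 775 TPM), S100P (22.0 to 220 TPM), CALCA (3.10 to 37.1 TPM), GDF15 (143 to 1101 TPM) and UNC13D (1.02 to 14.1 TPM). The largest falls reported here were in GAL, CCNB1, PLA2G3, FAM83D, CHRNA2, PIF1, PIMREG, MAF and PRR15L, with log2 changes from -3.48 ± 0.14 for GAL to -2.56 ± 0.10 for PRR15L. GAL encodes the neuropeptide galanin.

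All 37 ATF4 targets rose with Drug_CN27 (relative median 1.79), 33 of them at least 2-fold, with SLC3A2 going from 186 ± 0.238 to 1014 ± 51.9 TPM. The list passed camera at adjusted p = 3.9e-15 and kept its call at adjusted p = 0.0404 with an estimated correlation. Of 40 MYC and ribosome biogenesis genes, 36 fell and 1 rose (relative median -0.87), with LYAR, MYC, NCL and PA2G4 lower, at adjusted p = 7.74e-14 and likewise at adjusted p = 0.0404 with an estimated correlation. Of 26 cholesterol synthesis genes, 23 fell and 2 rose (relative median -1.07, adjusted p = 3.38e-10; adjusted p = 0.0508 with an estimated correlation). Among them FDFT1, squalene synthase, went from 357 ± 0.708 to 139 ± 0.862 TPM, and FDPS and EBP also fell.

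Of 52 G2/M genes, 49 fell and 1 rose (relative median -1.44, adjusted p = 5.61e-22; adjusted p = 0.136 with an estimated correlation), including TACC3, BIRC5 and PLK1. Of 52 G1/S genes, 48 fell and 1 rose (relative median -0.88, adjusted p = 6.1e-16; adjusted p = 0.0512 with an estimated correlation), including CDC45, DSCC1, RRM2 and MCM7. MKI67 fell by 2.14 ± 0.10 log2 and MYC by 1.28 ± 0.06 log2. Of 34 repair genes, 26 fell and 4 rose (relative median -0.71, adjusted p = 7.26e-07; adjusted p = 0.251 with an estimated correlation), with CHEK2, FANCA, CHEK1 and EXO1 lower. Of 36 androgen-response genes, 23 fell and 4 rose (relative median -0.77, adjusted p = 4.23e-07; adjusted p = 0.243 with an estimated correlation), with FKBP5 going from 717 ± 33.6 to 167 ± 11.3 TPM and with DBI and STEAP1 lower. KLK3 fell by 1.12 ± 0.18 log2.

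All 8 metal-response genes rose (relative median 1.93, adjusted p = 0.000186; adjusted p = 0.243 with an estimated correlation), with MT1E higher by 2.12 ± 0.08 log2 and with MT2A, MT1X and MT1G higher. Of 33 immediate early genes, 25 rose and 3 fell (relative median 0.86, adjusted p = 7.1e-05; adjusted p = 0.166 with an estimated correlation), led by FOS, DUSP1, KLF10 and ID1. Of 27 NRF2 targets, 17 rose and 3 fell (relative median 0.62, adjusted p = 0.00563; adjusted p = 0.166 with an estimated correlation), with NQO1, a quinone reductase, going from 62.5 ± 6.15 to 264 ± 6.84 TPM and with TXNRD1 and SQSTM1 higher. Of 35 lysosome and autophagy genes, 25 rose and 6 fell (relative median 0.36, adjusted p = 0.00986; adjusted p = 0.166 with an estimated correlation), with MAP1LC3B, GABARAPL1 and PSAP higher. Of 32 p53 targets, 18 rose and 3 fell (relative median 0.26, camera adjusted p = 0.0311, and adjusted p = 0.227 with an estimated correlation). CDKN1A was at 704 ± 17.4 TPM, and TP53INP1 and SESN2, which is also in the ATF4 list, were higher. Of 18 core histone genes, 10 rose and 1 fell (relative median 0.45, adjusted p = 0.043; adjusted p = 0.384 with an estimated correlation), with HIST1H2AC, HIST2H4A, HIST1H3H and HIST1H4H, all with close copies, higher.

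Of 54 respiratory chain genes, 32 fell and 4 rose (relative median -0.41, adjusted p = 7.23e-07; adjusted p = 0.339 with an estimated correlation), with ATP5MC1, NDUFB10, NDUFS6 and UQCRFS1 lower. Of 20 heat shock genes, 13 fell and 3 rose (relative median -0.36, adjusted p = 0.0103; adjusted p = 0.268 with an estimated correlation), with the mitochondrial chaperonins HSPD1 and HSPE1 and with FKBP4 and HSPB1 lower. Of 76 ribosomal protein genes, 35 fell and 10 rose (relative median -0.29, adjusted p = 0.000728; adjusted p = 0.474 with an estimated correlation), with RPL11, RPL23A, RPS9 and RPL7 lower. The lists of apoptosis regulators (16 higher and 5 lower of 30, adjusted p = 0.194), chromatin regulators (16 and 19 of 49, 0.194), mesenchymal genes (4 and 6 of 13, 0.163) and endoplasmic reticulum chaperones (12 and 13 of 26, 0.289) did not pass. Nor did those of glycolysis (10 higher and 11 lower of 30, 0.242), fatty acid synthesis (4 and 7 of 17, 0.15), interferon response (17 and 6 of 28, 0.194) or luminal markers (9 and 3 of 16, 0.313). The same held for neuroendocrine markers (5 higher and 6 lower of 14, 0.168), NF-kB targets (4 and 8 of 17, 0.164), xenobiotic response (3 and 3 of 8, 0.565), fibroblast markers (3 and 3 of 6, 0.681) and reference genes (5 and 8 of 17, 0.161). Basal markers were 3 higher and 1 lower of 4 tested and leukocyte markers 1 higher of 3, and ESAM did not pass. With median-of-ratios scaling the xenobiotic list had 2 higher and 4 lower genes and the leukocyte list 1 and 1. Adjusted over the list alone, 1 gene more was called in the lists of apoptosis, autophagy, glycolysis, MYC, neuroendocrine and xenobiotic genes, 1 gene fewer among ribosomal proteins, and the other lists kept their counts. The fibroblast list had a median of 0.07 with a mean of -0.13, and the chromatin and glycolysis lists medians of -0.08 and -0.09 with means of 0.02 and 0.07. Camera's direction was lower for all 3, and the fibroblast median turned to -0.09 with median-of-ratios scaling.

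The median gene moved by 0.15 log2 with Drug_CN27 under TPM and by -0.01 with median-of-ratios scaling, where the calls were 4503 higher and 4809 lower. H1FX passed as lower with that scaling (-0.31, adjusted p = 0.00612) and without Drug_CN27 replicate 2 (-0.19, adjusted p = 0.042), while the core histone list ended without Drug_CN27 replicate 2 (adjusted p = 0.0912) or with a pseudocount of 5 (0.0581), and the ribosomal protein and heat shock lists ended with quantile normalization (0.552 and 0.0604).

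The third comparison sets the compounds against each other, each at its own IC50, so a difference includes any difference of dose or time. H1FX was 1.18 log2 higher with Drug_CN27 than with Drug_0120 (95% interval 1.03 to 1.32; 0.55 after the GC correction). Of the 4 linker histone genes, 2 were higher and 2 lower, also with median-of-ratios scaling. MMP1 was at 0.548 ± 0.150 TPM with Drug_CN27 and 212 ± 0.306 TPM with Drug_0120 (log2 difference -7.11, 95% interval -7.36 to -6.86), and ARC, CGA, CES1 and MMP10 also differed by more than 5 log2. The genes furthest above Drug_0120 were HSPB6, a small heat shock protein at 516 ± 19.6 against 25.9 ± 2.15 TPM, SAMD11, PCK2, the readthrough transcript JMJD7-PLA2G4B, which shares reads with its neighbours and is uncertain, and UHRF1. Limma called 10234 of 13606 genes, 7034 higher with Drug_CN27 and 3200 lower, of which 2413 and 540 differed at least 2-fold. With median-of-ratios scaling the split was 5101 higher and 5254 lower, with quantile normalization 5014 and 5222, and after rescaling without ribosomal protein genes 5483 and 4708; the median gene differed by 0.26 log2 under TPM and by -0.01 with median-of-ratios scaling.

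Cell cycle genes were higher with Drug_CN27 than with Drug_0120. Of 52 G1/S genes, 47 were higher and 1 lower (relative median 0.95, adjusted p = 1.16e-06; adjusted p = 0.154 with an estimated correlation), with RRM2, UHRF1, E2F1 and E2F2 among them. Of 52 G2/M genes, 40 were higher and 4 lower (relative median 0.71, adjusted p = 0.000638; adjusted p = 0.384 with an estimated correlation), with CDC20 at 141 ± 10.8 TPM with Drug_CN27 and 30.6 ± 0.333 TPM with Drug_0120 and with CDCA3, PTTG1 and BUB1B higher. MKI67 differed by 1.06 log2 (95% interval 0.84 to 1.28). Of 37 ATF4 targets, 30 were higher and 5 lower (relative median 1.09, adjusted p = 0.000322; adjusted p = 0.142 with an estimated correlation), with the serine synthesis genes PHGDH, higher by 2.59 log2 (95% interval 2.42 to 2.75), and PSPH, and with PCK2 and CHAC1. Of 54 respiratory chain genes, 46 were higher and 1 lower (relative median 0.24, adjusted p = 0.000433; adjusted p = 0.468 with an estimated correlation), including NDUFB10, NDUFA13 and CYC1, and with median-of-ratios scaling 26 were higher and 7 lower. Of 30 glycolysis genes, 22 were higher and 5 lower (relative median 0.55, adjusted p = 0.0423; adjusted p = 0.263 with an estimated correlation), with ENO2, HK2, TPI1 and LDHA. Of 34 repair genes, 25 were higher and 3 lower (relative median 0.28, adjusted p = 0.0394; adjusted p = 0.486 with an estimated correlation), with FANCI, FANCL and BRIP1.

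Of 32 p53 targets, 27 were lower with Drug_CN27 than with Drug_0120 and 1 higher (relative median -1.01, adjusted p = 1.43e-11; adjusted p = 0.107 with an estimated correlation), with GDF15, PLK2 and BTG2. Of 33 immediate early genes, 24 were lower and 6 higher (relative median -1.78, adjusted p = 6.71e-10; adjusted p = 0.142 with an estimated correlation), with EGR1 at 74.5 ± 1.80 TPM against 706 ± 9.43 TPM and with DUSP4, ZFP36 and JUND. All 8 metal-response genes were lower (relative median -1.92, adjusted p = 4.84e-07; adjusted p = 0.22 with an estimated correlation), including MT1H, MT1G, MT2A and the zinc exporter SLC30A1. Of 18 core histone genes, 12 were lower and 2 higher (relative median -1.20, adjusted p = 6.37e-05; adjusted p = 0.263 with an estimated correlation), with HIST2H2BE, HIST1H4E, HIST2H2AA3 and HIST1H3H. Of 26 cholesterol genes, 15 were lower and 5 higher (relative median -0.74, adjusted p = 0.000127; adjusted p = 0.142 with an estimated correlation), with FDFT1 at 139 ± 0.862 against 463 ± 2.39 TPM and with INSIG1 and MSMO1. Of 76 ribosomal protein genes, 45 were lower and 5 higher (relative median -0.48, adjusted p = 6.71e-10; adjusted p = 0.384 with an estimated correlation), with RPL4, RPS4X, RPL21 and RPS9. Of 26 endoplasmic reticulum chaperones, 15 were lower and 7 higher (relative median -0.52, adjusted p = 0.00508; adjusted p = 0.263 with an estimated correlation), with MANF, DNAJB9, HSPA5 and SEC24D. Of 8 xenobiotic response genes, 5 were lower and 2 higher (relative median -0.95, adjusted p = 0.0368; adjusted p = 0.263 with an estimated correlation), with CYP1A1 at 78.7 ± 2.47 against 283 ± 1.95 TPM and with TIPARP, CYP1B1 and CYP1A2.

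The lists of androgen-response genes (26 higher and 9 lower of 36, adjusted p = 0.18), luminal markers (11 and 1 of 16, 0.0643), neuroendocrine markers (12 and 2 of 14, 0.101), chromatin regulators (33 and 9 of 49, 0.156) and interferon response (20 and 4 of 28, 0.18) did not pass. Nor did those of heat shock (14 higher and 5 lower of 20, 0.461), NRF2 targets (16 and 8 of 27, 0.834), fatty acid synthesis (10 and 4 of 17, 0.48), MYC and ribosome biogenesis (20 and 10 of 40, 0.475) or apoptosis (12 and 12 of 30, 0.18). The same held for autophagy (14 higher and 12 lower of 35, 0.122), NF-kB targets (7 and 5 of 17, 0.234), mesenchymal genes (7 and 5 of 13, 0.48), fibroblast markers (2 and 2 of 6, 0.363) and reference genes (8 and 4 of 17, 0.835). The lists of MYC, autophagy, mesenchymal and apoptosis genes had medians of 0.15, 0.14, 0.69 and -0.05 and means of 0.16, -0.05, 0.08 and 0.08, while camera's direction was lower. With median-of-ratios scaling the medians of the MYC, autophagy and reference gene lists turned to -0.15, -0.17 and -0.13, and the autophagy list passed as lower (adjusted p = 0.0259). The counts of higher and lower genes then turned to 10 and 20 for MYC, 3 and 18 for autophagy, 5 and 9 for NF-kB and 6 and 7 for reference genes, and were 10 and 16 for apoptosis and 1 and 2 for fibroblast genes. KLK3 differed by 1.23 log2 (95% interval 0.82 to 1.64) and MYC by 0.40 (0.26 to 0.55). Adjusted over the list alone, 1 gene more was called in the lists of xenobiotic, chromatin regulator, cholesterol and chaperone genes, and the other lists kept their counts. MYC no longer passed with median-of-ratios scaling (0.10, adjusted p = 0.196). The xenobiotic list ended with all 3 scalings (adjusted p = 0.158, 0.0899 and 0.121) and with the GC correction (0.127), the repair list with quantile normalization (0.0724) or without Drug_CN27 replicate 1 (0.0604), and the glycolysis list without Drug_CN27 replicate 2 (0.0532).

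The compounds' changes against vehicle were also set side by side. With both compounds 3576 genes rose, against 2143 for independent lists, and 3074 fell, against 1648, while simulated unchanged groups gave at most 1 gene in either direction. Fold changes correlated across genes at r = 0.661, with a simulated value of 0.501 from the shared vehicle libraries, and genes are not independent replicates. The covariance was 0.489 against a simulated 0.00644, a difference of 0.482. Signs matched for 71.7% of genes, against 66.6% in the simulation. Unchanged groups that share controls give about 0.501 and 66.6% by design. Both values therefore do not measure which part of 0.661 or 71.7% comes from the shared controls. The vehicle group has too few libraries to split, so some part of the excess in counts and signs from the shared controls stays open. The simulated covariance of 0.00644 against 0.489 argues against a large part from the spread between libraries of a group. A shift common to both vehicle libraries was not simulated and stays open. In 1442 genes the compounds went in opposite directions and differed from each other, 1223 of them lower with Drug_0120 and higher with Drug_CN27 and 219 the reverse. With median-of-ratios scaling 3151 genes rose and 3568 fell with both compounds, and 665 and 590 were opposite and differed, in the same order; after rescaling without ribosomal protein genes these counts were 4045, 2835, 836 and 366.

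**Figure D2:**
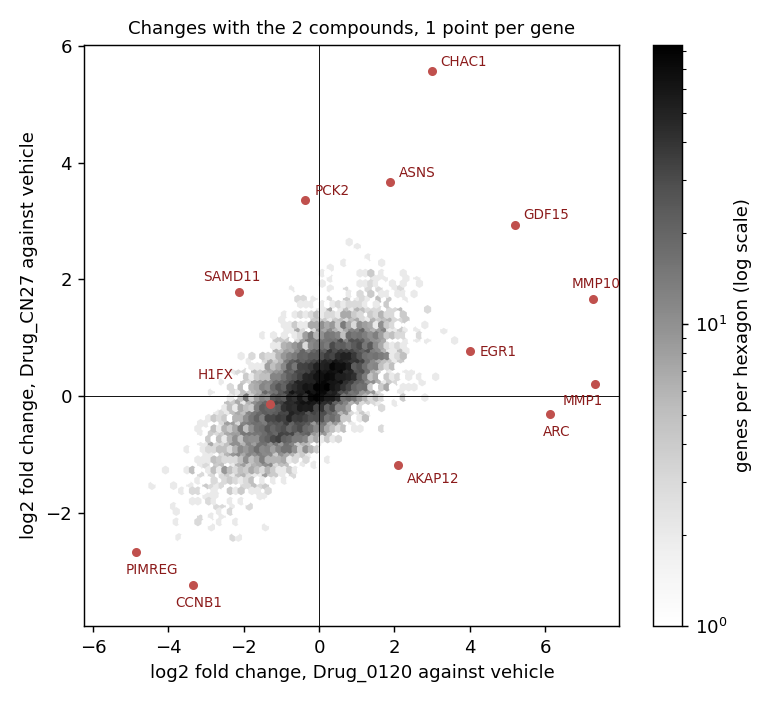
Log2 fold change against vehicle with Drug_0120 (horizontal axis) and Drug_CN27 (vertical axis) for the 13606 tested genes, shaded by the number of genes per hexagon on a log scale, with some named genes as red points. The correlation across genes was 0.661, and SAMD11 and AKAP12 lie in the quadrants of opposite change.

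**Figure D3:**
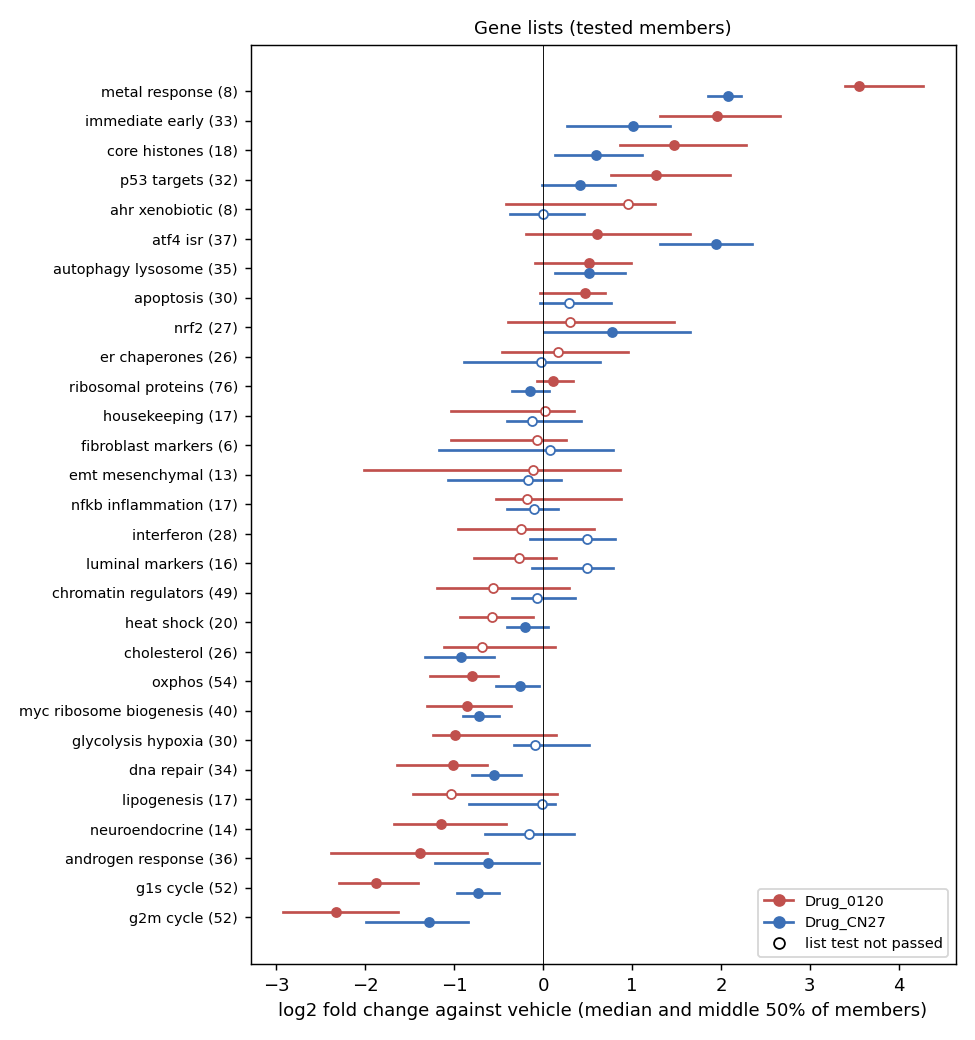
Log2 fold change against vehicle of the tested members of 29 gene lists, with the median (point) and the middle 50% of members (line) for Drug_0120 (red) and Drug_CN27 (blue); filled points passed the camera test. The G2/M list had medians of -2.33 and -1.29, and the ATF4 list 0.60 and 1.94.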

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

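The tests of TPM scaling on H1-10 and of GC slopes against replicates, and the GC correction, were chosen only after the results they measure were seen.

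The ribosomal protein list passed as higher with Drug_0120 and as lower with Drug_CN27, and its median differed by -0.22 log2 between them. With an estimated correlation neither call held (adjusted p = 0.713 and adjusted p = 0.474), the first was also lost without vehicle replicate 1 (0.0889) or Drug_0120 replicate 2 (0.115), and the other with quantile normalization (0.552). Fry in a single direction called it for neither compound (adjusted p = 0.0906 and 0.0738). In 1442 genes the calls against vehicle were opposite and the difference between the compounds also passed. Of these, 21 changed at least 2-fold each way, for example AKAP12 (20.6 TPM in vehicle, 90.7 with Drug_0120 and 8.54 with Drug_CN27) and CLGN (22.9, 5.58 and 70.2 TPM), which were chosen after their values were seen. Genes outside the table, which no comparison uses, held 28.4% of TPM with Drug_0120, above the 19.3% and 18.1% of the vehicle libraries.

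The H1FX transcript fell with Drug_0120 by 1.31 log2. Median-of-ratios scaling left a log2 change of -1.19 (95% interval -1.36 to -1.01), which argues against TPM scaling as the whole cause. H1FX transcripts are GC-rich, at 68.6% against a median of 49.4%, and after the GC correction the log2 change was -0.57 (95% interval -0.66 to -0.48, limma adjusted p = 4.28e-06). The rule set before the test counted an estimate of -0.5 or lower with adjusted p under 0.05 against GC content as the cause, and the estimate met it. The interval extends above -0.5, which that rule did not consider, and the fall became smaller. A GC effect on a large part of the fall can therefore not be told apart from an effect of the compound on this gene. The difference between the compounds was 0.55 ± 0.04 log2 (SE) after the correction.

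Fold changes with Drug_0120 fell with GC content, by -0.29 log2 per 10 points of percent GC (Spearman's rho across genes -0.253), and the median gene above 60% GC was at -0.60 log2 and that at or below 40% at 0.23. The steepest slope between replicates was 0.113 in size, and the slope with Drug_0120 was 2.55 times as steep. Replicate slopes compare single libraries, while slopes with a compound compare means of 2 libraries, so the measures are not alike. Each group had only 2 libraries, so larger chance differences between libraries of a group are not excluded. With Drug_CN27 the slope was -0.15 (Spearman's rho -0.231), only a little steeper than between replicates, so it cannot be told apart from such differences. Without the 830 tested genes of the fixed lists the slope with Drug_0120 kept 107% of its size. These are too few of the 13606 genes to carry much of it, so a part of cell cycle and other co-regulated genes stays open. A preparation effect that followed the groups stays open, since the labels name no batch, and so does an effect of the compound on GC-rich genes, which was not tested.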

How the results depend on the processing

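The GC correction and the 2-fold counts were chosen after seeing the data. Over all alternatives the counts of called genes stayed within 1.5 times the reported value, except that testing Drug_CN27 against a 1.2-fold change left 5926 genes, by its stricter hypothesis. A pseudocount of 5, which shrinks the changes of low genes, gave 2548, 796 and 1491 genes at 2-fold for Drug_0120, Drug_CN27 and their difference. Leaving out 1 library at a time gave 10340 to 11194 genes for Drug_0120, 8326 to 9452 for Drug_CN27 and 9393 to 10111 for the difference; the lone library was then assumed to vary like the other groups. The correlation of the compounds' fold changes was 0.645 to 0.671 over these fits, 0.648 and 0.675 with pseudocounts of 0.1 and 5, 0.647 without a filter and 0.646 with the GC correction, with or without the replicate block; the cause was not tested. With the GC correction, the calls were 5964 higher and 5394 lower for Drug_0120, 5055 higher and 4764 lower for Drug_CN27 and 5148 and 5623 for the difference.

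Camera with an estimated correlation called 0 lists for Drug_0120, 2 for Drug_CN27 and 0 for the difference, against 16, 16 and 14 with the preset value. Fry called 27 lists for Drug_0120, 24 for Drug_CN27 and 28 for the difference in a single direction, and 29 lists in either direction in all 3 comparisons. Among lists that either test called, fry and camera differed in direction for 4. These were NF-kB targets with Drug_0120 (median -0.18), fibroblast markers with Drug_CN27 (0.073), and apoptosis (-0.054) and MYC genes (0.15) between the compounds. Lists called by neither test are not counted here. Fry does not compare a list with other genes, and the cause was not tested. Apart from these tests, 13 of 16, 12 of 16 and 11 of 14 list calls held in all settings, while 3, 1 and 5 further lists passed in some. Without a filter on low values these were the mesenchymal list for Drug_CN27 (adjusted p = 0.0245) and, for the difference, the chromatin regulator (0.0364), luminal (0.0271) and NF-kB (0.0271) lists. For the difference, the luminal list also passed without Drug_CN27 replicate 1 (0.0466), the androgen-response list with the GC correction (0.0489), and the autophagy list with the GC correction (0.0163) and after rescaling without ribosomal protein genes (0.0342). Among named genes, 3335 of 3346 results under alternatives were on the same side of the threshold with the same direction, 6 passed newly and 5 no longer passed. The ribosomal protein list had no value when its genes were removed.

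Samples with the same replicate number deviated together at r = 0.164, 0.150 and 0.110 across genes, and at 0.134, 0.104 and 0.078 after the GC correction. The GC slope of replicate 1 less replicate 2 was negative in vehicle (-0.062), Drug_0120 (-0.051) and Drug_CN27 (-0.113). A shared preparation is therefore not excluded, but 2 pairs per comparison cannot settle it, so the reported fit has no block. The replicate block gave 11526, 10284 and 10894 called genes. Under it the core histone list with Drug_CN27 no longer passed (adjusted p = 0.0584), with the GC correction added neither the p53 list with Drug_CN27 (adjusted p = 0.0551) nor the xenobiotic list between the compounds (0.162) passed, and H1FX with Drug_CN27 passed (-0.13, adjusted p = 0.0156), as did the heat shock list with Drug_0120 (0.0396) and the luminal list between the compounds (0.0481). Depth is unknown, so what it limits cannot be stated.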

Other observations

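The ZNF family of zinc-finger genes, most of them encoding DNA-binding proteins, and the class of single-exon genes were chosen after their values were seen, as was the GC correction used in the tests. Of 466 tested ZNF genes, 349 rose and 50 fell with Drug_0120 (median 0.75 log2), 287 rose and 45 fell with Drug_CN27 (median 0.39), and 261 rose with both. Between the compounds, 272 were lower and 66 higher with Drug_CN27. The direction of the median held with the 3 other scalings, from 0.86 to 0.99 log2 for Drug_0120 and from 0.23 to 0.41 for Drug_CN27. Genes with 1 annotated exon also rose more often than they fell with Drug_0120, with 225 of 407 higher and 115 lower (median 0.40). With Drug_CN27, 209 of them were higher and 74 lower (median 0.29).

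A rise of ZNF genes with Drug_0120 could follow from their low GC content (median 43.1% against 49.4% for all genes) or low expression (11.3 against 20.8 TPM). After the GC correction the ZNF median was 0.77 log2 above that of all genes, beyond the central 95% of 10000 random lists matched on GC (-0.13 to 0.07). The uncorrected median of 0.75 lay beyond that of 10000 lists matched on mean expression (-0.27 to -0.03). Both tests argue against these sources, while reads shared between ZNF paralogs stay open and were not tested.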
